A study of Mus musculus with 4 samples.

How the data were processed

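The libraries were made from EpCAM-positive cells sorted from dissociated tongue epithelium of embryonic day 16 embryos, 2 control and 2 labelled Ring1a/b 2KO. Per the labels' protocols, tissue was digested with dispase, collagenase and trypsin, a small amount of total RNA was reverse transcribed and amplified, and libraries were sequenced as 100-nucleotide single reads. The deposited files give, per gene and library, a whole-number read count and an FPKM value made by the authors. Per the submitters' processing notes, TopHat2 2.0.13, Cufflinks 2.2.1, HTSeq 0.6.1 and DESeq2 1.6.3 were used with the mouse build mm10; which tool made which column, the gene annotation and the strand setting are not given in the sources used here. Reads of overlapping genes and close paralogs may therefore be shared or lost. Exons of some genes named in the text overlap those of another annotated gene, so their values are uncertain to that extent. They include Rnf2, Zic1, Hoxa7, Hoxd11, Gli1, Ncam1, Itpr3, Krt5, Krt6a, Krt6b, Krt80, Top2a, Sfrp2 and Kremen2. Also among them are Col5a1, Ryr1, Elavl3, Shh, Krt8, Klk14, Wfdc5, Rbbp7, Nrn1, Malat1, Map2, Ttn and Pmel. Amplification before sequencing means that reads are not independent molecules, so intervals and floors cover counting error only.

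The deposited counts were compared with edgeR 4.0.16 in R 4.3.3: TMM normalization, the filterByExpr filter with the group, and the quasi-likelihood test (two-sided) of genotype alone, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Every adjusted p of a gene is from this test unless another is named. Of 24453 genes in the files, 19211 had a count and 15336 were tested. The biological coefficient of variation was 0.313. CPM values use the TMM-scaled library sizes. Both libraries of one group lay on one side of both of the other for 57.7% of tested genes, against 33.3% by chance, and for all 1827 called genes. For a gene with 0 counts in a group, the fold was computed against 3 counts over the group (0.0801 CPM in control, 0.0793 CPM in the 2KO-labelled group) and is a lower bound; for 1 to 3 counts the ratio is given with its 95% counting interval. Symbols were matched to the GENCODE annotation of the same build: 23753 directly, 288 through an older symbol, 44 to several genes and 368 not at all, and 24026 were used with coordinates.

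Before the data were examined, 27 gene lists, the alternatives and the rule for named genes were fixed, together with the main test. The rule names Ring1 and Rnf2, then the 12 genes in each direction with the greatest absolute log2 fold change among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, leaving out predicted gene models and pseudogenes. It adds the called members of each list by smallest p, at most 6, or 2 members where none was called, 10 genes chosen beforehand, and the 2 most abundant members of each list of other cell types; the text gives examples of these. Lists were tested with camera of limma 3.58.1 (two-sided) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with adjustment over the 27 lists. They were tested again with a correlation estimated from the data, and with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes. With the preset correlation 6 lists were higher and 6 lower. With an estimated correlation 0 were called, with 2 at an unadjusted p under 0.05; fry called 2, the Hox list and the other transcription factors.

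The steps were tested on simulated counts drawn from these libraries' means and sizes for the 2KO against control comparison. Spread followed a trend with expression level, and changes were planted only in genes with a mean of at least 1 CPM. The recovery given next thus does not cover genes of lower level, and no rate covers genes whose spread departs from that trend. Among 14911 genes run, edgeR recovered 38% of 100 genes changed by 2-fold and 73% of 100 changed by 4-fold, with 0 of wrong sign, and 4.31% of its calls were unchanged genes. Among 14956 genes run, a simulated list of 30 genes raised 2-fold was called with the preset correlation (adjusted p = 8.91e-22) and missed with the estimated one (adjusted p = 0.217), and neither called any of 27 unchanged lists. The simulated genes were drawn independently of each other, whereas the estimated correlation in the data was 0.517 for the basal keratinocyte list. These runs therefore cannot show how often the preset correlation calls lists of correlated genes. Alternatives were other scalings (RLE, upper quartile), DESeq2 1.42.0, limma-voom, other filters, the replicate number as a block, limma-trend on the deposited FPKM values with pseudocounts of 1 and 0.1, and each library left out. A fit without Rn45s, Malat1 and Lars2 and a fit with a GC content and transcript length offset were chosen after seeing the data. No value column was left unused for want of a sample.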

Results

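RNA was measured in the lining epithelium of the mouse tongue on embryonic day 16. Cells carrying EpCAM, an adhesion molecule of the epithelial surface, were sorted from the front of the tongue, without the circumvallate papilla at the back. The 4 libraries fell into 2 groups of 2, control and Ring1a/b 2KO. In the second genotype Ring1 (Ring1a) is deleted in the germline and Rnf2 (Ring1b) is a conditional allele cut by a Cre recombinase under the Krt14 promoter. Both genes encode catalytic subunits of Polycomb repressive complex 1, a chromatin complex that keeps developmental genes silent, and the comparison asks what that complex does in this epithelium. Control replicates 1 and 2 held 20624055 and 16256569 counts, and 2KO-labelled replicates 1 and 2 held 18039767 and 20545262. A count was present for 17299, 16810, 17781 and 17516 genes, in the same order. The ribosomal RNA precursor gene Rn45s took 16.7% and 15.3% of the counts in the control libraries. In the 2KO-labelled libraries it took 22.9% and 20.2%, a difference that goes with every gene group below. Replicates differed by far more than counting error (chi-square per degree of freedom 28.7 in the control and 22.7 in the 2KO-labelled group), so neither pair was one library deposited under both names. The labels do not say that replicates came from separate embryos, so p-values measure only the spread between these libraries, which may be technical.

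Neither targeted gene was lower in the libraries labelled 2KO. Ring1 (chromosome 17, 34020792 to 34024680, mm10) stood at 9.02 and 8.57 CPM, a read count scaled to library size, in the control libraries and at 16.8 and 15.0 CPM in the 2KO-labelled libraries. Rnf2 (chromosome 1, 151458004 to 151500955) stood at 34.0 and 51.3 CPM in control and at 62.9 and 62.4 CPM in the 2KO-labelled libraries. Neither difference passed the test: the log2 fold change was 0.85 for Ring1 (standard error 0.312, adjusted p = 0.101) and 0.56 for Rnf2 (standard error 0.221, adjusted p = 0.126). Rnf2 was called higher without control replicate 2 (log2 fold change 0.89, adjusted p = 0.00853) and after a correction for GC content and length (0.82, adjusted p = 0.0311). Gene-level counts cannot show the loss of part of a gene, and the deleted part is not in the labels, so these values leave the genotype unchecked. Every direction below is therefore that of the libraries labelled 2KO against the libraries labelled control.

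Of 15336 genes tested, 1073 were higher and 754 lower in the 2KO-labelled libraries, together 11.9% of the genes tested. By at least 2-fold, 821 were higher and 307 lower. Of the 1073 genes that rose, 187 (17.4%, exact 95% interval 15.2% to 19.8%) had a mean under 1 CPM in control, beside 17.9% of uncalled genes with a positive log2 fold change. Under 0.5 CPM these shares were 13.9% and 8.82%, and under 2 CPM they were 25.35% and 28.49%. The comparison with uncalled genes thus turns with the level chosen. Of the 754 that fell, 36 (4.775%) had a mean under 1 CPM in the 2KO-labelled libraries, beside 9.67% of uncalled genes with a negative one. The comparison planned beforehand, of both sets by their control level, tells nothing, since a gene under 1 CPM in control can hardly be called lower. No read was counted in either control library for 46 of the genes that rose, and none in either 2KO-labelled library for 2 of the genes that fell. With limma-voom the share under 1 CPM in control among genes that rose was 10.1%. Without control replicate 1, 1643 genes were higher, and 498 were lower by at least 2-fold. With limma-trend on the deposited FPKM values, 627 were higher and 260 lower, a split of 70.7% higher against 58.7% on the counts, and with no filter on low FPKM values no gene passed, with 3764 at an unadjusted p under 0.05. Among genes named below, the calls of Krt5, Krt14, Perp, Cenpf, Cenpe, Cdkn1b, Ptch1, Rbbp7, Itpr3, Arhgap29, Postn, Egr1, Krt23, Vstm2a, Wfdc5, Lypd5 and Mt4 also ended on filtered FPKM values with a pseudocount of 1 or 0.1.

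Hox genes, which encode the transcription factors that set position along the body axis, rose together in the 2KO-labelled libraries. Of 31 tested, 19 rose, 1 fell and 11 did not pass; adjusted over the list alone, 25 rose and 1 fell. Hoxd13 was at 0.0538 ± 0.00683 CPM in control and 34.6 ± 4.03 CPM in the 2KO-labelled libraries (SD, n = 2 in each group, as for every mean below), a ratio of 651 with a 95% counting interval of 180 to 5377 (adjusted p = 1.35e-05). Hoxd8 and Hoxc8 had 0 counts in both control libraries and reached 15.4 ± 2.25 and 10.9 ± 0.979 CPM, at least 194-fold and at least 136-fold higher against a floor of 3 counts over the group. Hoxa7 went from 0.0490 ± 0.0693 to 21.2 ± 7.15 CPM, a ratio of 404 (counting interval 111 to 3339), and Hoxd11 from 0.0980 ± 0.139 to 15.3 ± 2.03 CPM. Genes of all 4 clusters were among those that rose. Summed over a cluster, Hoxa genes (chromosome 6, 52155590 to 52260880) went from 2.35 to 50.3 CPM, with 6 of 10 tested genes higher. Hoxb genes (chromosome 11, 96194316 to 96368256) went from 3.81 to 26.4 CPM, with 3 of 6 higher. Hoxc genes (chromosome 15, 102921103 to 103036852) went from 20.4 to 48.0 CPM, with 5 of 8 higher and 1 lower. Hoxd genes (chromosome 2, 74668310 to 74765142) went from 0.25 to 83.3 CPM, with 5 of 7 higher. The gene that fell was Hoxc13, singled out after its values were seen, from 19.4 ± 6.54 to 8.03 ± 1.63 CPM (log2 fold change -1.27, adjusted p = 0.0361).

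**Figure D1:**
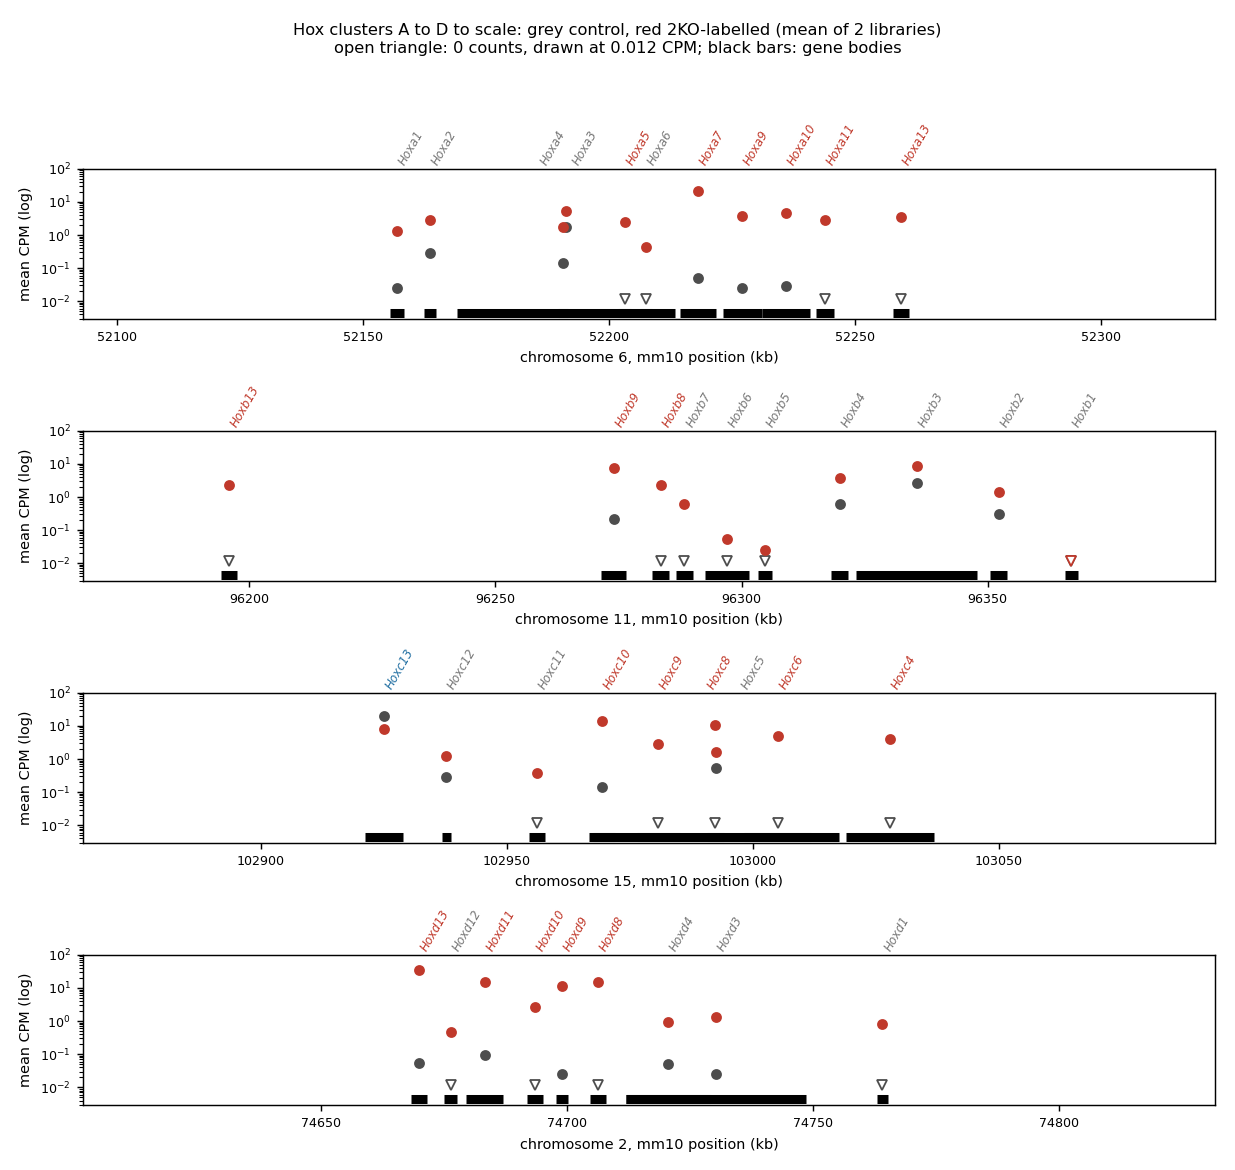
Mean CPM on a log axis of every Hox gene of clusters A to D at its mm10 position in kb, control in grey and 2KO-labelled in red, with gene bodies as black bars and means of 0 counts as open triangles at the foot of the axis. Names in red are genes called higher and the name in blue, Hoxc13, is the 1 called lower; the Hoxd genes sum to 0.25 CPM in control and 83.3 CPM in the 2KO-labelled libraries.

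Of the other developmental transcription factors, nearly all that passed the test moved in the same direction. Of 133 tested from a list of 190, 61 rose, 1 fell and 71 did not pass; adjusted over the list alone, 84 rose and 4 fell. Zic1, a zinc-finger factor of neural and somite development (chromosome 9, 91358058 to 91365810), had 0 counts in both controls and 33.5 ± 6.86 CPM in the 2KO-labelled libraries, at least 423-fold higher. Gata4, a factor of heart and gut development, likewise went from 0 counts to 11.8 ± 0.916 CPM, at least 147-fold higher. Onecut2 rose from 1.63 ± 0.397 to 39.3 ± 2.68 CPM (log2 fold change 4.58, standard error 0.318, adjusted p = 4.4e-05), and Pax3, a neural crest and muscle precursor factor, from 0.583 ± 0.0772 to 15.6 ± 1.97 CPM (log2 fold change 4.72, standard error 0.483, adjusted p = 0.000213). The gene that fell was Pax9, singled out after its values were seen, from 437 ± 31.8 to 199.9 ± 6.78 CPM (log2 fold change -1.13, adjusted p = 0.000763). The median log2 fold change was 7.10 over the Hox list, or 5.16 with genes of 0 to 3 counts at their bound or raw ratio, and 2.40 over the other factors. Against all other genes both lists were higher with a preset correlation between genes (camera, two-sided, adjusted p = 4.23e-20 and 2.31e-23), and neither call held with an estimated correlation (adjusted p = 0.194 for each). In the same libraries the Rn45s share was higher, as given above, and the median of 10 endothelial markers was 1.20 on the log2 scale.

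The 12 genes with the greatest increases by the naming rule were mostly developmental transcription factor genes, and 10 of them had 0 counts in both control libraries. Besides those already named they were Mira, at 18.3 ± 0.719 CPM and at least 228-fold higher, Pax2, at 7.33 ± 1.39 CPM and at least 92.3-fold higher, and Zic2, at 6.45 ± 1.02 CPM and at least 81.1-fold higher. Vstm2a, Nkx2-9 and Hoxc6 were at least 78.2-fold, 65.0-fold and 63.0-fold higher, and Hoxd9 had a ratio of 453 (counting interval 80.9 to 17940). No coordinates were matched for Mira.

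**Figure D2:**
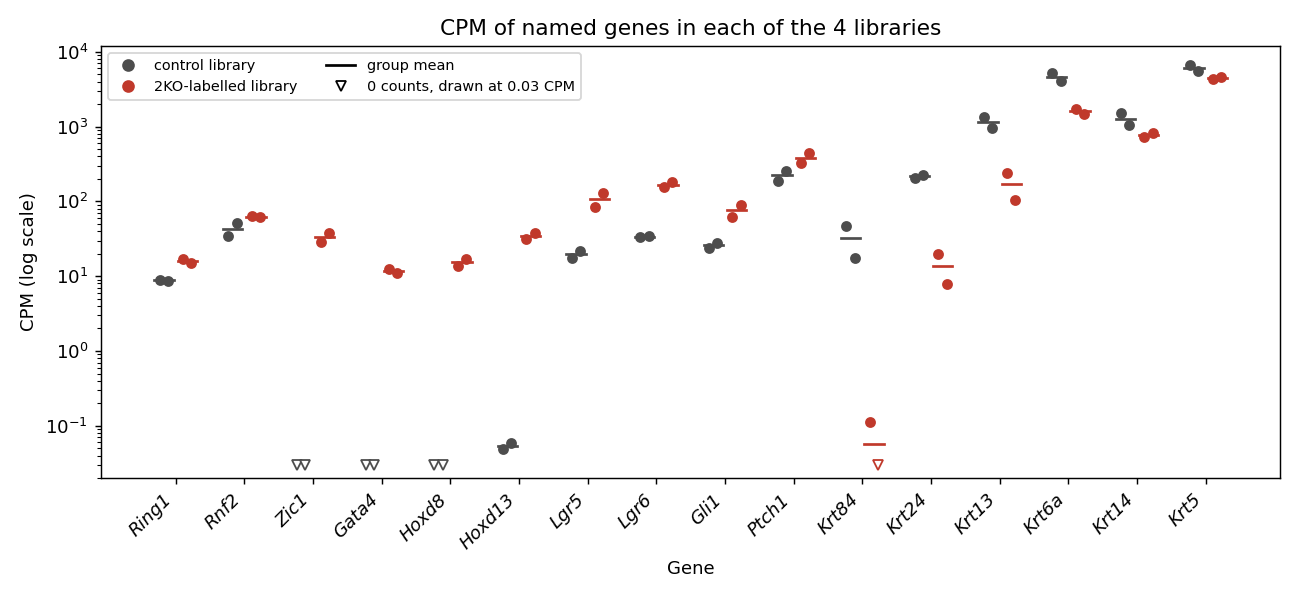
CPM on a log axis of genes named in the text, each point a library, control in grey and 2KO-labelled in red, with a bar at the mean of each group's 2 libraries and open triangles for 0 counts. Ring1 and Rnf2 stand higher in the 2KO-labelled libraries without passing the test, Zic1 and Hoxd8 go from 0 counts to 33.5 and 15.4 CPM, and Krt13 and Krt84 lie lower.

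Most of the tested genes of the differentiating upper layers of the epithelium fell. Of 32 genes of suprabasal and cornified keratinocytes tested from a list of 45, 18 fell, 1 rose and 13 did not pass; adjusted over the list alone, 22 fell and 1 rose. Krt13, the main keratin of the suprabasal layers of oral epithelium (chromosome 11, 100117327 to 100121566), fell from 1152 ± 292 to 172 ± 95.2 CPM (log2 fold change -2.75, standard error 0.324, adjusted p = 0.000491). Dsg1a, a desmosomal cadherin, fell from 243 ± 59.7 to 31.1 ± 18.1 CPM, and Tgm3, a transglutaminase that cross-links the cornified envelope, from 72.4 ± 16.98 to 15.0 ± 4.14 CPM. The gene that rose was Lor, which encodes the envelope protein loricrin and was singled out after its values were seen, from 3.31 ± 1.36 to 14.2 ± 3.83 CPM (adjusted p = 0.0129). Hard keratins and other genes of the filiform papillae, the horny spines of the tongue surface, fell in 9 of 14 tested from a list of 21, with none higher; adjusted over the list alone, 9 fell and 0 rose. Krt84, a hard keratin, fell from 32.3 ± 20.7 to 0.0567 ± 0.0802 CPM, a ratio of control to 2KO of 637 (counting interval 176 to 5264), and Krt36 gave a ratio of 96.03 (26.2 to 799). Krt24 fell from 215.5 ± 11.4 to 13.9 ± 8.44 CPM, and Krt6b and Krt6a, close paralogs between which reads can be split wrongly, from 63.5 ± 20.99 to 3.41 ± 2.23 CPM and from 4637 ± 761 to 1617 ± 178 CPM. Both lists were lower than other genes (camera adjusted p = 5.55e-07 and 1.11e-06), and neither call held with an estimated correlation (adjusted p = 0.532 for each). In the same libraries the Rn45s share was higher and the list of replication-dependent histones was lower (camera adjusted p = 0.0017, or 0.532 with an estimated correlation).

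The 12 genes with the greatest decreases included Krt84 and Krt6b of the hard keratin list, and 6 of the 12 had 0 counts in a 2KO-labelled library. No theme was tested over the 12. Sdr9c7 and Alox12b, enzymes of the skin's lipid barrier, fell from 8.24 ± 0.201 to 0.135 ± 0.0503 CPM (log2 fold change -5.88, adjusted p = 0.000698) and from 28.5 ± 4.31 to 1.47 ± 0.157 CPM (log2 fold change -4.27, adjusted p = 6.94e-05). Mt4, a metallothionein of stratified epithelia, fell from 15.8 ± 1.54 to 0.766 ± 1.08 CPM (adjusted p = 0.0133), a call that ended with DESeq2 (adjusted p = 0.263). Il1r2, a decoy receptor for interleukins, gave a ratio of control to 2KO of 139 (counting interval 37.97 to 1149). Endou, Wfdc5, Lypd5 and Idi2 fell by log2 fold changes of -4.15, -5.30, -4.62 and -4.05. Klk14 and Pou2af1 were also called lower, at log2 fold changes of -5.60 and -5.59, but Klk14 lost its call with limma-voom (adjusted p = 0.0774) and without control replicate 1 (log2 fold change -4.29, adjusted p = 0.0678) and Pou2af1 with limma-voom (0.108) and without control replicate 2 (-3.95, adjusted p = 0.188).

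Of 23 tested basal keratinocyte and adhesion genes 7 fell, none rose and 16 did not pass, and 8 of the 23 had a positive log2 fold change. Adjusted over the list alone, 11 fell and 1 rose. With upper-quartile scaling 5 fell and 1 rose. Dsc3, a desmosomal cadherin, fell from 671 ± 89.9 to 329 ± 2.63 CPM, and Perp, a desmosomal membrane protein, from 2262 ± 113 to 1167 ± 141 CPM. Genes that did not pass included Trp63, Itga6 and Col17a1, at log2 fold changes of 0.0012, 0.34 and 0.10. Krt15 and Dsg3, at -0.38 and -0.85, did not pass either. The basal keratins Krt5 and Krt14 fell from 6127 ± 906 to 4471 ± 103 CPM (log2 fold change -0.45, adjusted p = 0.0392) and from 1277 ± 340 to 773 ± 77.2 CPM (log2 fold change -0.72, adjusted p = 0.0248). Both keratins lost their calls without control replicate 1 (adjusted p = 0.112 and 0.0674), and Krt5 also with upper-quartile scaling (0.0558). The list was lower than other genes (camera adjusted p = 0.0426), but not with an estimated correlation (adjusted p = 0.655), without control replicate 1 (0.324), without 2KO-labelled replicate 1 (0.154), with upper-quartile scaling (0.0506) or on log2(FPKM + 0.1) (0.055). Epcam, the sorting marker, was at 205 ± 22.7 and 230.3 ± 20.4 CPM (adjusted p = 0.542). Of 13 tested genes of the periderm, the embryonic surface layer, 4 fell and none rose (4 and 0 adjusted over the list alone, camera adjusted p = 0.217), among them Krt6a and Arhgap29, which fell from 446 ± 58.8 to 223.5 ± 66.2 CPM. Of 7 keratin genes listed mainly for simple epithelium, 5 of which are also in another list, Krt18 rose, Krt80 and Krt23 fell and 4 did not pass (1 and 2 adjusted over the list alone, camera adjusted p = 0.376). The Krt23 call ended with DESeq2 (adjusted p = 0.0675). Krt8 was at 28.1 ± 4.88 and 28.0 ± 4.49 CPM.

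**Figure D3:**
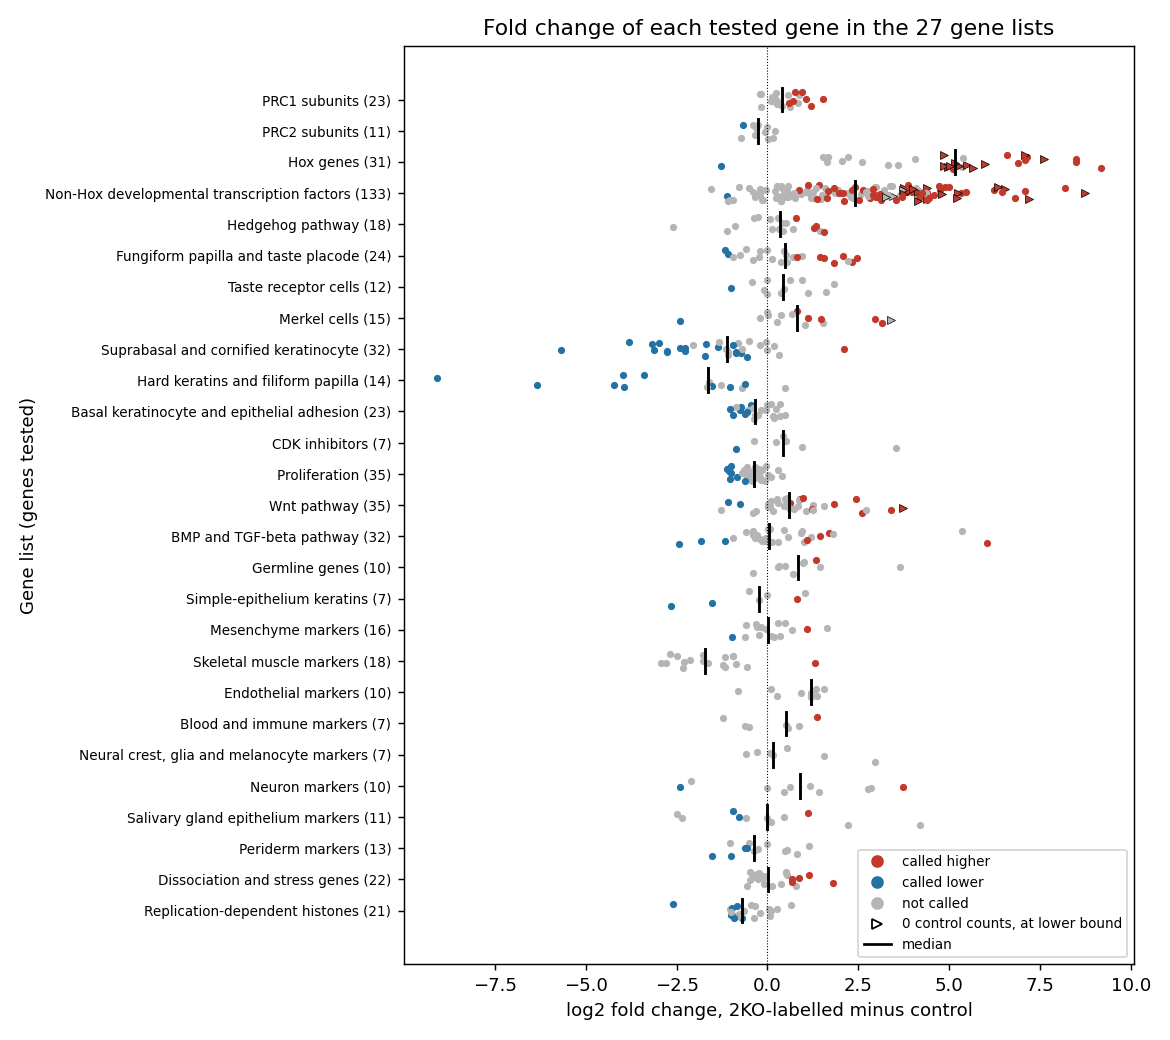
Log2 fold changes, 2KO-labelled minus control, of the tested members of the 27 gene lists, each point a gene, with a bar at each list's median. Red and blue points are genes called higher and lower, triangles are genes with 0 control counts drawn at their lower bound, and with them so placed the Hox list has a median of 5.16.

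Of 24 tested genes of the fungiform papillae, which carry the taste buds of the front of the tongue, 7 rose, 2 fell and 15 did not pass. Adjusted over the list alone 10 rose and 2 fell. For the list the camera adjusted p was 0.0539, or 0.59 with an estimated correlation. The list was called higher with limma-voom (0.00627), without 2KO-labelled replicate 1 (0.0182), with no filter on low counts (0.0229), with the 1 CPM filter (0.0444) and on FPKM values (0.0161 to 0.0374). Lgr5 and Lgr6, receptors for R-spondin found on epithelial stem cells, rose from 19.6 ± 3.16 to 107 ± 31.4 CPM (log2 fold change 2.46, adjusted p = 0.000185) and from 33.8 ± 1.19 to 168 ± 18.9 CPM (log2 fold change 2.31, adjusted p = 6.71e-05). Bmp7 rose from 50.6 ± 2.23 to 137.5 ± 23.3 CPM and Bmp2 fell from 126 ± 9.68 to 56.4 ± 5.70 CPM. Sox2, a factor of the taste placode, was at 34.7 ± 3.68 and 30.2 ± 3.55 CPM (adjusted p = 0.617). Of 18 Hedgehog pathway genes 4 rose and none fell, also adjusted over the list alone. For this list the camera adjusted p was 0.228, or 0.627 with an estimated correlation, 0.0339 with limma-voom and 0.0281 to 0.0423 on FPKM values. After the GC content and length correction its test direction was lower. Gli1, a transcriptional target and effector of the pathway, rose from 25.8 ± 2.56 to 75.8 ± 20.7 CPM (log2 fold change 1.55, adjusted p = 0.0017). Ptch1, the receptor, rose from 222 ± 47.0 to 384 ± 83.2 CPM (adjusted p = 0.0245), a call lost without 2KO-labelled replicate 2 (0.116). The ligand Shh was at 10.8 ± 1.99 and 17.6 ± 3.50 CPM (adjusted p = 0.167).

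Of 35 tested Wnt pathway genes 9 rose, 2 fell and 24 did not pass; adjusted over the list alone, 14 rose and 2 fell. The secreted Wnt inhibitors Sfrp2 and Sfrp1 rose from 10.9 ± 0.895 to 66.3 ± 10.5 CPM and from 123 ± 1.69 to 243 ± 20.8 CPM. The ligand Wnt4 fell from 376 ± 33.0 to 224 ± 0.0578 CPM, and Wnt10a was also called lower. The others called higher were Axin2, Nkd1, Rspo1, Kremen2, Dkk3 and the ligands Wnt3 and Wnt8b. Log2 fold changes were 0.894 for Axin2, 2.44 for Nkd1, 3.41 for Rspo1 and 1.24 for Wnt3, and Wnt8b had 0 control counts. The direction of Wnt signalling was not tested. The list was higher than other genes (camera adjusted p = 0.000244), but not with an estimated correlation (adjusted p = 0.532) or after the GC content and length correction (0.116). Of 32 BMP and TGF-beta pathway genes 4 rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.509). Bmp3 rose from 30.7 ± 5.37 to 98.2 ± 23.7 CPM, and Id1, a target of BMP signalling, fell from 37.0 ± 20.0 to 10.3 ± 0.834 CPM. Of 15 genes of Merkel cells, the touch receptor cells of epithelia, 5 rose and 1 fell (6 and 1 adjusted over the list alone). Ncam1, which neurons also express, rose from 9.36 ± 2.77 to 82.2 ± 8.82 CPM, and Tubb3, a tubulin of neurons, fell from 11.99 ± 5.09 to 2.28 ± 0.630 CPM. The Merkel list was higher (camera adjusted p = 0.0171), but not with an estimated correlation (adjusted p = 0.532), without control replicate 1 (0.0789), without 2KO-labelled replicate 2 (0.182) or on filtered FPKM values (0.112 and 0.124). Atoh1, the master regulator of Merkel cells, had too few counts to be tested, with 0 and 3 in the control and 4 and 38 in the 2KO-labelled libraries. Of 12 taste receptor cell genes none rose and 1 fell, Itpr3, a calcium channel of taste transduction, from 268 ± 65.4 to 133 ± 14.8 CPM (0 and 1 adjusted over the list alone, camera adjusted p = 0.325).

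Of 35 proliferation genes 7 fell and none rose, also when adjusted over the list alone, and 28 did not pass. Top2a, a topoisomerase of dividing cells, fell from 587 ± 19.2 to 284 ± 43.4 CPM (log2 fold change -1.05, standard error 0.153, adjusted p = 0.00167), and Cenpf and Cenpe, kinetochore proteins, from 225 ± 23.8 to 105 ± 7.49 CPM and from 206 ± 16.1 to 102 ± 3.77 CPM. The list was lower (camera adjusted p = 7.06e-05), but not with an estimated correlation (adjusted p = 0.532) or with fry (adjusted p = 0.0891). Of 21 replication-dependent histone genes, whose near-identical copies make single values uncertain, 7 fell and none rose; adjusted over the list alone, 9 fell. The histone list was lower (camera adjusted p = 0.0017), but not with an estimated correlation (adjusted p = 0.532). Of 7 CDK inhibitors, brakes of the cell cycle, none rose and Cdkn1b fell, also adjusted over the list alone, from 26.3 ± 1.19 to 14.4 ± 1.45 CPM (adjusted p = 0.0488; list, camera adjusted p = 0.406). The Cdkn1b call ended without control replicate 1 (adjusted p = 0.078) and without 2KO-labelled replicate 1 (0.241) or 2 (0.103), with RLE (0.0505) or upper-quartile scaling (0.0599), without Rn45s, Malat1 and Lars2 (0.0531) and after the GC content and length correction (0.0953). Cdkn2a, a tumour suppressor and known Polycomb target, was at 0.294 ± 0.416 and 3.59 ± 0.943 CPM (log2 fold change 3.54, adjusted p = 0.085), and passed without control replicate 1 (adjusted p = 0.000795), with DESeq2 (0.0176) and with no filter on low counts (0.00655).

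Some other subunits of the Polycomb complexes differed between the groups. Of 23 PRC1 genes 7 rose and none fell, also when adjusted over the list alone. Bcorl1 and Bcor rose from 27.1 ± 2.23 to 77.8 ± 2.64 CPM (log2 fold change 1.52, adjusted p = 0.000623) and from 89.1 ± 4.38 to 203 ± 42.8 CPM (log2 fold change 1.19, adjusted p = 0.00217), and Phc1 from 46.8 ± 3.64 to 89.9 ± 6.503 CPM. The PRC1 list was higher (camera adjusted p = 0.00686), but not with an estimated correlation (adjusted p = 0.547), without control replicate 1 (0.0789), without 2KO-labelled replicate 2 (0.127) or after the GC content and length correction (0.188). Of 11 PRC2 genes 1 fell and none rose, also adjusted over the list alone (camera adjusted p = 0.217). It was Rbbp7, a histone-binding protein shared with other complexes, from 179 ± 6.77 to 113 ± 1.93 CPM, a call that ended without 2KO-labelled replicate 1 (adjusted p = 0.0836) or 2 (0.0617) and after the GC content and length correction (0.158). Of 10 tested germline genes only Tdrd1, a gene of the piRNA pathway, rose, from 14.1 ± 0.433 to 36.0 ± 4.19 CPM. Adjusted over the list alone 2 rose. The germline list had a camera adjusted p of 0.0548, or 0.532 with an estimated correlation and 0.0242 after the GC content and length correction.

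Markers of cells that the EpCAM sort should remove were present in both groups. Of 16 mesenchyme genes 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.915). Sparc, the most abundant, was at 920.3 ± 45.1 and 748 ± 126 CPM (adjusted p = 0.225), Col5a1 rose from 81.2 ± 6.07 to 171 ± 10.7 CPM (adjusted p = 0.0538 after the GC content and length correction), and Postn fell from 37.1 ± 0.618 to 18.7 ± 6.90 CPM, a call lost without 2KO-labelled replicate 1 (adjusted p = 0.27), with upper-quartile scaling (0.0513) and after the GC content and length correction (0.0669). Skeletal muscle genes had a median log2 fold change of -1.71 over 18 genes (camera adjusted p = 0.0426), which rested on control replicate 2: without it the median was 0.30 (adjusted p = 0.467). The muscle list was also not called with an estimated correlation (adjusted p = 0.627), limma-voom (0.0708) or the 1 CPM filter (0.0789), or without 2KO-labelled replicate 1 (0.0656). Of its genes Ryr1 rose and none fell, and none passed adjusted over the list alone. Ryr1 lost its call without control replicate 2 (adjusted p = 0.0666) or either 2KO-labelled replicate (0.169 and 0.132) and after the GC content and length correction (0.237). None of 10 endothelial genes passed, also adjusted over the list alone, while the list was higher (median 1.20, camera adjusted p = 0.0426; adjusted p = 0.532 with an estimated correlation). The endothelial call also ended without control replicate 1 (0.0597), control replicate 2 (0.0818) or 2KO-labelled replicate 2 (0.0832), with limma-voom (0.109) or upper-quartile scaling (0.0506), and after the GC content and length correction (0.134). Cdh5 was at 9.16 ± 0.898 and 21.1 ± 12.1 CPM (adjusted p = 0.0684) and passed without 2KO-labelled replicate 1 (0.00109), control replicate 1 (0.0404) or control replicate 2 (0.0201), with DESeq2 (0.0371) and with no filter on low counts (0.00452). Of 7 blood and immune genes Cd68, of macrophage lysosomes, rose from 16.6 ± 6.62 to 43.1 ± 5.76 CPM (1 and 0 adjusted over the list alone, camera adjusted p = 0.65). None of 7 neural crest, glia and melanocyte genes passed, and 1 rose adjusted over the list alone (camera adjusted p = 0.376). Of 10 neuron genes 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.204); they were Elavl3, whose call ended without 2KO-labelled replicate 1 (adjusted p = 0.163) and with limma-voom (0.0731), and Tubb3. Cells of the salivary gland are epithelial, and the sort could keep them. Of 11 salivary gland genes 1 rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.708). Their median log2 fold change was -0.02 and the mean 0.08, with a test direction of lower. Sox9, also a factor of other epithelia, rose from 126.5 ± 33.8 to 277 ± 48.3 CPM. Of 22 dissociation and stress genes 5 rose and none fell (6 and 0 adjusted over the list alone, camera adjusted p = 0.481), among them Egr1, from 2982 ± 231 to 4743 ± 227 CPM, and Egr3, from 57.3 ± 18.7 to 200.3 ± 23.8 CPM. After the GC content and length correction Egr1 did not pass (adjusted p = 0.0969).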

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

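The fits without Rn45s, Malat1 and Lars2 and with a GC content and length offset were chosen after the result was seen; all other alternatives were fixed before the data were examined. No gene called on the counts was called in the opposite direction under any alternative. With no filter on low counts 1242 genes were lower. Limma-trend on log2(FPKM + 1) gave 627 higher and 260 lower genes, 522 and 170 of them by at least 2-fold, and log2(FPKM + 0.1) gave 472, 186, 430 and 144. Log2(FPKM + 1) with no filter gave 0 higher and 0 lower genes, 0 and 0 of them by at least 2-fold, with 3764 at an unadjusted p under 0.05; the cause was not tested. The share of higher calls was 58.7% with TMM, 65.6% with upper-quartile scaling and 70.7% and 71.7% on filtered FPKM.

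Leaving out each library in turn, which assumes that the lone library of a group varies like the other group, gave 839 to 1643 higher genes, 345 to 498 lower by at least 2-fold, and 3 to 7 lists called higher. The log2 fold change of Rnf2 then ranged from 0.31 to 0.89, and it was 0.818 with the GC content and length correction. The replicate numbers share only a number: the deviations of same-numbered libraries had a correlation of -0.0232. With the replicate block 1156 genes were higher and 880 lower, and the germline list was called (adjusted p = 0.0379). With an estimated correlation camera called 0 lists higher and 0 lower, with 2 at an unadjusted p under 0.05, and fry called 2 higher and 0 lower. A simulated list was also missed with the estimate, but its genes were drawn independently, so it cannot decide which setting suits correlated lists.

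Directions that turned were those of genes and lists not called on the counts, except the muscle list. The log2 fold change of Map2, close to 0, became 0.0029 with RLE, 0.045 with upper-quartile scaling, 0.028 with limma-voom, 0.0016 with the 1 CPM filter, 0.015 with the replicate block, 0.14 with log2(FPKM + 1) with and without the filter, 0.185 with log2(FPKM + 0.1) and 0.015 without Rn45s, Malat1 and Lars2. That of Krt8 became 0.0046, 0.047 and 0.000703 with RLE, upper-quartile scaling and DESeq2, 0.0035 with the 1 CPM filter, 0.181 with log2(FPKM + 1) with and without the filter, 0.19 with log2(FPKM + 0.1) and 0.016 without Rn45s, Malat1 and Lars2. The median log2 fold change of the mesenchyme list was 0.016 with no count filter, where only the test direction turned to lower. With the GC content and length correction that median was -0.149. The median of the blood list was -0.634 with no count filter and -0.116 on unfiltered FPKM. With the GC correction those of the Hedgehog and stress lists were 0.158 (test direction lower) and -0.036. With each library left out, medians ranged from -0.20 to 0.26 for mesenchyme, -1.26 to 1.03 for blood, -0.20 to 1.53 for neurons, -2.20 to 0.30 for muscle, -0.13 to 0.57 for stress genes and -0.18 to 0.27 for neural crest. Log2 fold changes ranged from -0.27 to 0.36 for Map2, -0.18 to 0.19 for Krt8, -0.60 to 0.17 for Erbb3, -0.30 to 1.5 for Dcx, -2.42 to 0.27 for Ttn, -1.84 to 0.20 for Actc1, -0.31 to 0.72 for Pmel and -4.15e-05 to 0.63 for Dcn. Of other values of named genes under the alternatives, 1749 kept their side of the threshold and direction, 257 lost and 26 gained a call; for lists these were 386, 43 and 14. With 16256569 to 20624055 counts per library, a 2-fold change was recovered for 38% of simulated genes with a mean of at least 1 CPM.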

Other observations

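The tests of GC content and length, of few reads, of the mesenchymal explanations, of fewer suprabasal cells, of random placement and of filtered neighbours were chosen only after the differences between the groups were seen; for GC content and length and for the filtered neighbours the bounds were written before the values they measure were computed.

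Over all genes in the files, 51 were under 1 CPM in both control libraries and at 5 CPM or more in both 2KO-labelled libraries. The opposite pattern was seen for 9. Of the 51, 7 were Hox genes, 13 other listed transcription factors and 31 in neither list. The lists do not hold every developmental transcription factor, and Dmrt3, Fezf1 and Sall1 are among the 31. The most abundant of those 31 in the 2KO-labelled libraries, named here after their values were seen, were Trank1, at 34.3 and 36.1 CPM, C130021I20Rik, at 21.4 and 29.6 CPM, Elfn1, a synaptic adhesion protein, at 24.0 and 24.7 CPM, Mira, given above, and Nrn1, at 18.3 and 12.9 CPM. No theme was tested over the 31 genes, and of the 10 tested genes of the neuron list fixed beforehand 1 rose and 1 fell (camera adjusted p = 0.204). Of the 9 genes that went the other way 2 were hard keratins, Krt35 and Krt84.

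The first pattern is the rise of Hox and other developmental transcription factor genes, 80 of them called. A correction for a smooth trend with GC content and length was fitted. After that correction 75 of the 80, or 93.8%, were still called, with a median log2 fold change of 5.05 before and after. Of all 1073 genes called higher, 1065 could be tested after the correction and 832 were still called. The 80 were chosen for being called, so their large changes could hardly be lost and the share still called cannot decide. The unchanged median shows only that the fitted smooth trend did not carry their change. Noise of genes with few reads would part libraries of one group as often as libraries of different groups, but of 229 listed genes at least 27 were under 1 CPM in the control and at 5 CPM or more in the 2KO-labelled library of each such pair, against 0 between the control libraries and 1 in each direction between the 2KO-labelled libraries; the ratio of genes gained to genes lost, 5.67 over all genes and 4.43 outside the lists, partly restates the pattern and decides nothing. More mesenchymal cells of the kind already in the controls would raise their markers with the Hox genes, but the summed mesenchyme markers in the higher 2KO-labelled library were 1.09 times those of the lower control library and the greatest ratio of any of the 16 markers was 3.14, of Pdgfrb, while the called Hox genes rose 261-fold and all 39 Hox genes in the files, called or not, 7.76-fold. Over the other factors tested, called or not, the median log2 fold change was 2.40, against 0.0232 over the mesenchyme markers (SD 0.668). Over the 108 with a mean of at least 1 CPM over all 4 libraries it was 2.24. A factor silent in control can pass either filter through the 2KO-labelled libraries alone, so both medians may be raised. Only 52 of the 190 listed reached 1 CPM in both control libraries, against all 16 markers. The comparison of medians therefore cannot decide for these factors. Their summed CPM rose only 1.44-fold over all 190 listed and 3.17-fold over the 61 called. RNA of mesenchymal cells of another make-up cannot be told apart. The change in summed mesenchyme markers, -58.5 CPM, has a standard error of 131 CPM beside a Hox gain of 166.8 CPM. Loss of Polycomb silencing stays open and was not tested. The labels name the Ring1a/b genotype, which gene-level counts leave unchecked.

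The second pattern is the fall of suprabasal and hard keratin genes, 27 of them called. After the GC content and length correction 26 of the 27, or 96.3%, were still called, with a median log2 fold change of -2.41 before and -2.55 after. Of all 754 genes called lower, 750 could be tested after the correction and 527 were still called. The 27 were likewise chosen for being called. Fewer suprabasal cells with no change inside cells would leave markers of basal cells alone level or higher. Of the 23 listed basal and adhesion genes 7 were called lower and 0 higher, also with RLE and without Rn45s, Malat1 and Lars2. After the GC content and length correction these were 10 and 0. Dsc3 and Perp, at log2 fold changes of -1.03 and -0.95, are adhesion genes that were not shown to be limited to basal cells. The other 16 did not pass, and 8 of the 23 had a positive log2 fold change, among them Trp63, Itga6 and Col17a1. This explanation cannot be told apart for that reason. Further, with upper-quartile scaling 5 were lower and 1 higher, and the calls of Krt5 and Krt14 rested on control replicate 1. The genotype difference that the labels name stays open and was not tested.

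The third pattern is that genes called higher lay next to each other in the genome more often than chance gives. There were 117 neighbouring pairs, against a mean of 74.5 and a highest value of 105 in 10000 random placements among genes of similar level (permutation p = 1e-04, one-sided, the smallest they can give). Without Hox genes, pairs of one family name and overlapping genes, 86 pairs remained against a mean of 61.5, a 95% range of 48 to 77 and a highest value of 92 (permutation p = 0.001, one-sided), so gene families and shared reads may account for part and cannot be told apart from the rest. Genes called lower showed 62 pairs against a mean of 37.4 (permutation p = 2e-04, one-sided), and 40 against 32.4 without such pairs (permutation p = 0.1, one-sided), and whether the directions differ was not tested. Loss of Polycomb silencing through the genotype that the labels name stays open and was not tested.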
